A study of Medicago truncatula with 16 samples.

How the data were processed

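RNA from leaves of 3 groups of plants was read on 16 one-colour arrays, 8 on each of 2 slides that were scanned separately. The deposited scanner files hold spot intensities on a linear scale, written by Agilent Feature Extraction 10.7.3.1 per the file headers. The processed signal in them is an intensity after the background correction of that program, and no normalization between arrays had been applied, as far as the values show. Per the labels' protocols, total RNA was labelled with Cy3 by a low-input amplification kit. A second table that the authors deposited holds 1 intensity per probe and array. Its columns have 1 distribution, with a median of 119.7 in each of the 16 columns, so it was taken to be linear and quantile normalized; both are inferred from the values, and how the authors made it is not given in the sources used here.

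Values were computed from the scanner files in R 4.3.3. The 1319 control spots were left out, as were spots marked as outliers unless all spots of a probe were so marked; spots of 1 probe (at most 5) were averaged as log2 of the processed signal, and each array's 75th percentile was subtracted. The arrays of a biological replicate were then averaged, which gave 9 replicates. A probe was tested if it was well above background in every replicate of at least 1 group, in at least 1 of 2 arrays where a replicate had 2. This kept 30110 probes and left out 13493. The 9 replicates of all groups were fitted together with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with a threshold of 0.05. A log2 fold change is a difference of group means, and its SE is the moderated one. P-values measure the spread between 3 biological replicates per group.

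A probe not well above background on any array of a group has only a bound there. On each array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background is taken. The bounded fold is the brighter group's mean over the mean of these. For the genes named, it lay at or close to the plain fold. It is therefore no firm lower limit, and another background correction can give smaller folds. Where several probes stand for a gene, the 1 with the highest mean over all arrays gives the gene's values; in totals of genes, a gene counts as called if any of its tested probes passed.

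Probes carry transcript accessions and no gene names. A RefSeq gene table for the assembly MtrunA17r5.0-ANR, matched without versions, gave a symbol to 7036 of 43603 probes, for 4423 genes. The table pairs accessions with symbols, nearly all of them plain locus numbers, and holds no product descriptions. The 29 gene lists fixed in advance were searched for by keyword in descriptions, and 0 of them matched a tested probe, so no gene list could be tested. No array build is named, so no coordinates are given.

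Before the data were examined, these choices were fixed: the groups, the fit, the other settings to try and the rule for naming genes. Per comparison, the rule takes the 8 largest rises and 8 largest falls among genes that pass, whose groups do not overlap and which are above background on at least 1 array of each group, plus up to 3 genes per direction with only a bound, by the brighter mean. If none passes, it takes the 10 genes with the smallest p. It also required a gene description. As none was at hand, that condition was dropped, the rule was applied to genes with a symbol, and at most 2 rising and 2 falling transcripts without a symbol were added per comparison.

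The other settings fixed then were quantile normalization, normexp background correction (offset 50), no filter, a filter for probes well above background on all 16 arrays, the authors' deposited table, all 16 arrays with replicate as a random block, with and without slide, each slide alone, replicate number as a block, only the groups compared, array weights, a variance trend with robust estimation, stricter thresholds and leaving out each replicate. The files used here hold a median spot signal and not the mean that the normexp alternative named, so it was run on the median signal. Alternatives chosen after seeing the data left out the 2 arrays with the most probes well above background, left out control 3 and mycorrhized 2 together, and added array row as a term.

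The fit, which by then had been run on the measured data, was tested on simulated data for the 30110 probes, with the observed means and spreads and 200 changed probes. In the simulated comparison of mycorrhized against control, it recovered 20.0% of probes changed by 1 log2 unit, 70.0% by 2, 100.0% by 4 and 100.0% by 6, with 9 calls among 29910 unchanged probes. In that of phosphate against control it recovered 20.0%, 70.0%, 94.0% and 98.0%, with 5 such calls. Shared controls were simulated 100 times with unchanged groups, for 3 controls and, after seeing the data, for 2 controls with the spread of the fit without control 3. All replicates, controls included, were drawn anew with the fitted spread of each probe, and probes were independent of each other.

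The median background signal was 21.0 to 29.5 on 15 arrays and 170.0 on the slide 1 array of mycorrhized 3, where 81.9% of probes were well above background. The slide 2 array of phosphate 1 had 76.4%, and the other arrays had 59.9% to 73.6%. Arrays of 1 replicate correlated at 0.985 to 0.996 across probes. The median log2 fold change over all tested probes was 0.05, 0.07 and -0.02 for mycorrhized against control, phosphate against control and mycorrhized against phosphate.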

Results

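Leaf transcript levels were measured in Medicago truncatula, a model legume, on 16 one-colour Agilent arrays labelled with Cy3. All plants were fed a nutrient solution free of phosphate. Control plants received a mock inoculum of soil with leek roots. Mycorrhized plants received the same kind of soil with Rhizophagus irregularis, an arbuscular mycorrhizal fungus that colonises roots and passes phosphate to its host. Phosphate plants received the mock inoculum and a weekly dose of 5 mM NaH2PO4. Leaves came from plants 4 weeks old, kept in 16 h of light and 8 h of dark. Each of the 3 groups had 3 biological replicates, read on 5 control, 5 mycorrhized and 6 phosphate arrays. Control 1 and mycorrhized 2 had 1 array each, and the other 7 replicates had 2, on separate slides. Control 1 is therefore absent from slide 1, and mycorrhized 2 from slide 2. Between 26107 and 35714 of 43603 probes per array were well above background, and 30110 probes were tested. The number of arrays, and above all of biological replicates, limits the precision of each value. The design asks what root colonisation and phosphate feeding each do to leaf transcripts, and where the 2 treatments differ.

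The median SD was 0.09 (log2) between arrays of 1 replicate and 0.31 between biological replicates of a group. Control 3 stood apart from the other controls. Across probes, which are not independent replicates, it correlated at 0.944 with control 1 and 0.962 with control 2, but at 0.985 with mycorrhized 1 and 0.980 with mycorrhized 3. Mycorrhized 2 correlated more closely with control 2, at 0.980, than with mycorrhized 1, at 0.975, or mycorrhized 3, at 0.959. With control 1, however, it correlated at 0.965, less than with mycorrhized 1. The phosphate replicates correlated with each other at 0.984 to 0.991. On the slides, every phosphate replicate and control 3 lay in array row 2, and controls 1 and 2 and every mycorrhized replicate lay in row 1.

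**Figure D1:**
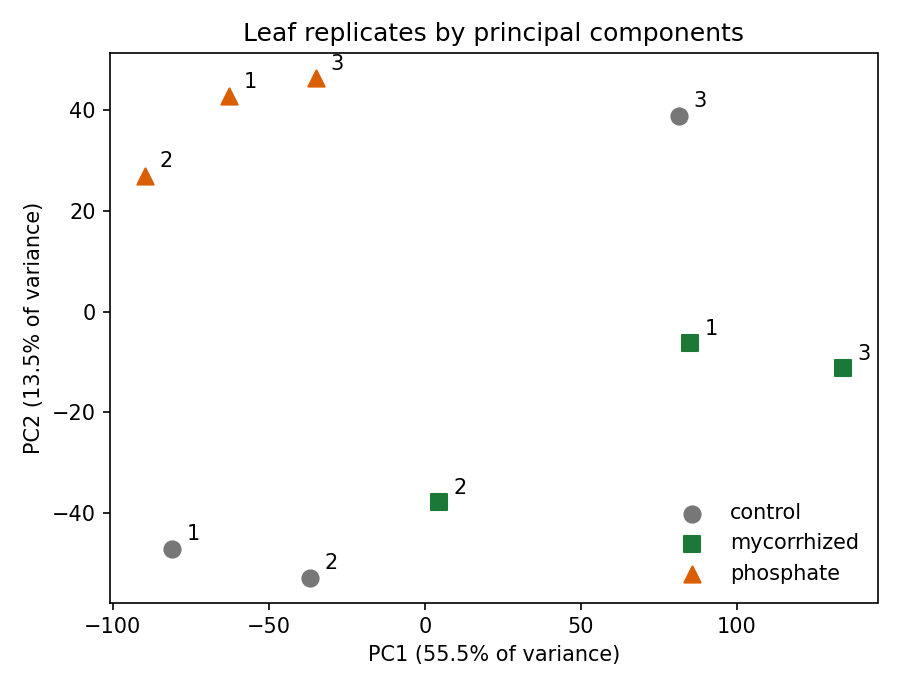
Principal components of the 9 biological replicates over all tested probes, with PC1 (55.5% of the variance) on the x axis and PC2 (13.5%) on the y axis, and the replicate number beside each point. Control 3 lies at 81.3 on PC1, near mycorrhized 1 at 84.9, while controls 1 and 2 lie at -80.8 and -36.9. On PC2 it lies at 38.9, among the phosphate replicates at 27.0 to 46.4 and away from mycorrhized 1 at -6.2.

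Phosphate feeding lowered a small set of leaf transcripts by large factors. The transcript TA20559_3880 went from a normalized log2 signal of 5.34 ± 0.35 (SD, n = 3) in control leaves to -0.52 ± 0.37 in phosphate leaves, a log2 fold change of -5.86 (SE 0.25, 58.1-fold lower), and both other probes for it changed alike, at -5.96 and -5.83. CB893723 was 62.3-fold lower (log2 fold change -5.96, SE 0.48). Of the genes with a symbol, LOC11412329 fell most, by 4.73 on the log2 scale (SE 0.44), from -0.76 ± 0.32 to -5.49 ± 0.85. LOC11437869 had a log2 fold change of -2.86, LOC11434679 of -1.81 and LOC11414718 of -1.14, the last with all 3 of its probes called. The other probe of LOC11437869 had -1.68 and was not called. No product description was at hand for these genes, so what they encode is not stated.

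Fewer transcripts were higher with phosphate. LOC11418309 rose from -7.45 ± 0.80 to -4.29 ± 0.19 (SD, n = 3), a log2 fold change of 3.16 (SE 0.37), and was well above background on 2 of 5 control arrays. DQ139345 rose by 3.33 (SE 0.38) and TC194277 by 2.48 (SE 0.26). LOC11414005 and LOC11414535 were not well above background on any control array. Their bounded folds in phosphate over control leaves were 21.4 and 12.7, close to the plain folds of 21.9 and 12.8. With normexp correction both were much smaller, as given below. By the rule for naming, all 3 phosphate values lay on 1 side of all 3 control values in each transcript named for this comparison.

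In all, 44 probes for 36 transcripts passed an adjusted p of 0.05 between phosphate and control leaves (limma with Benjamini-Hochberg adjustment), 8 higher and 36 lower with phosphate. The lowest adjusted p was 0.000116, and LOC11434679 had 0.00407, LOC11412329 0.00913, LOC11414718 and LOC11418309 0.0287, and LOC11437869 0.0346. Groups did not overlap for 16.9% of tested probes, against 10% by chance on average over splits of the replicates. With a difference of at least 2 log2 units, 239 probes did not overlap as labelled and 242 in the highest other split. The count was 230 without control 3, 19 and 20 without controls 1 and 2, 22 and 28 without mycorrhized 1 and 3, and 21, 21 and 20 without phosphate 1, 2 and 3. It was 19 on slide 1 alone, which lacks control 1, and 36 on slide 2 alone, which lacks mycorrhized 2. In a fit to all 16 arrays, with replicate as a random block, it was 266, and with slide added as a term it was 195. Slide thus lowered the count, and the rise over 44 came with the fit to single arrays. That fit takes 1 correlation between arrays of a replicate for all probes. TA20559_3880, CB893723 and LOC11434679 kept their calls under each of 16 alternatives, LOC11418309 and LOC11437869 lost theirs under 13, and the others lost theirs under 2 to 10. Control 3 is the only control in row 2, so array row as a term compares phosphate leaves with control 3 alone. It cannot tell row from the deviation of that control. With array row as a term, a setting chosen after seeing the data, 37 probes passed (16 higher, 21 lower), only 15 of them among the 44; of the named transcripts, TA20559_3880, CB893723, LOC11434679, LOC11414535 and DQ139345 kept their calls and 6 lost them, with log2 fold changes of 4.15 for DQ139345 and 3.86 for LOC11414005. With normexp background correction the log2 fold changes of dim transcripts were smaller, at 0.99 for LOC11418309, 2.63 for DQ139345, 1.25 for TC194277, 1.27 for LOC11414005, 1.06 for LOC11414535, -1.73 for LOC11437869, -4.26 for CB893723 and -3.14 for LOC11412329, of which DQ139345, CB893723 and LOC11412329 still passed. On slide 1 alone LOC11414535 had 4.30.

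For most probes lower with phosphate, mycorrhized leaves lay near control leaves. Probes lower or higher with phosphate were chosen by that difference, which enlarges it, and both comparisons share the controls. For the 36 probes lower with phosphate, the median log2 fold change of mycorrhized against control leaves was -0.12, against -3.32 for phosphate, and 33 lay within 1 log2 unit of control. Over all tested probes the SD of the mycorrhized against control value was 0.63. Of the 36, 8 had an unadjusted p under 0.05 in that comparison (limma). LOC11412329 was the lowest of them in mycorrhized leaves, with a log2 fold change of -5.18 (SE 0.44) against control and an adjusted p of 0.0885, which does not pass. For the 8 probes higher with phosphate, the median log2 fold change of mycorrhized against control leaves was 1.24, against 2.98 for phosphate. Choosing these probes favours low control values, which raises both medians, and no value for unchanged probes was computed. Between mycorrhized and control leaves 6 of the 8 had an unadjusted p under 0.05 (limma), but no probe passed, with a lowest adjusted p of 0.120.

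**Figure D2:**
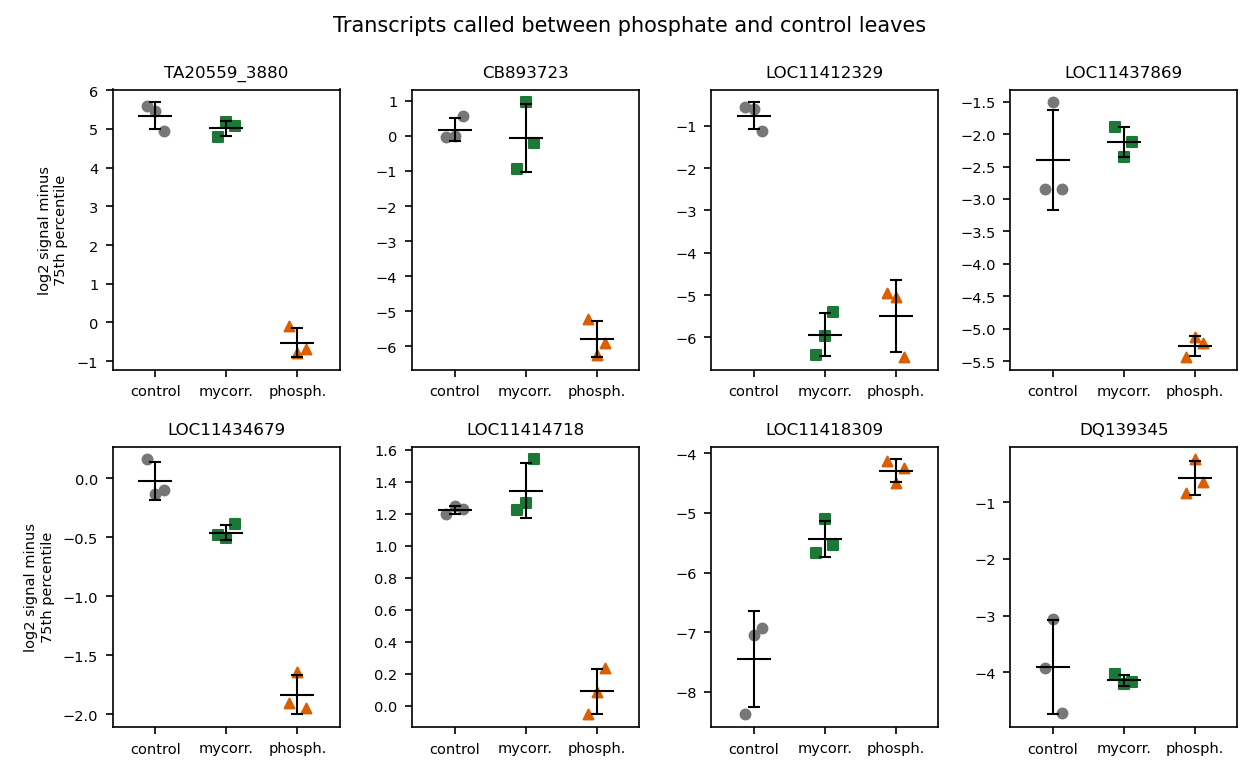
Normalized log2 signal (y axis, log2 signal minus the array's 75th percentile) of 8 transcripts called between phosphate and control leaves, by group (x axis); points are the 3 biological replicates, horizontal bars the mean and error bars the SD. TA20559_3880 stands at 5.34 in control and -0.52 in phosphate leaves, and LOC11412329 is low in both treated groups.

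More probes were called between mycorrhized and phosphate leaves. LOC11427346 had the largest rise among genes that passed on their brightest probe and were above background on some array of each group, at 0.04 ± 0.97 (SD, n = 3) against -6.61 ± 0.59, a log2 fold change of 6.65 (SE 0.86). LOC11414355 differed by 5.29 (SE 0.85), LOC11417531 by 4.93 (SE 0.71), LOC11438646 by 4.39 (SE 0.67) and LOC11441531 by 4.12 (SE 0.64), with all 7 probes for LOC11441531 called. LOC11442809 at 4.03, LOC11443517 at 3.70 and LOC11417986 at 3.67 completed the 8 largest rises. In phosphate leaves, LOC11438646 was well above background on 1 of 6 arrays and LOC11427346 and LOC11442809 on 3, so these folds rest on dim values. LOC11437154, LOC11429355 and LOC11415986 were not well above background on any phosphate array. Their bounded folds in mycorrhized over phosphate leaves were 393, 27.5 and 11.8, at or close to the plain folds. With normexp correction all 3 were much smaller, as given below. The bound for LOC11437154 was 175-fold without mycorrhized 3 and 793-fold without mycorrhized 2, and that for LOC11429355 was 17.8-fold without mycorrhized 3. Among transcripts with no symbol, XM_003592090 was higher by 6.16 (SE 0.98) and EY475147 by 5.93 (SE 0.88).

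Differences in the other direction were smaller among named genes. LOC11414005 was lower in mycorrhized leaves by 2.91 (SE 0.54, log2 fold change -2.91) and was well above background on 1 of 5 mycorrhized arrays. LOC11432675 had a log2 fold change of -2.11 (SE 0.38), LOC11407282 of -1.92, LOC11431822 of -1.75, LOC11442101 of -1.65, LOC11412813 of -1.62, LOC11443098 of -1.56 and LOC11427949 of -1.36. LOC11414535 was not well above background on any mycorrhized array. Its bounded fold in phosphate over mycorrhized leaves was 5.89, the same as its plain fold. BG646527 and TA29873_3880, which have no symbol, had log2 fold changes of -5.24 (SE 0.97) and -4.02 (SE 0.57). Of 5 mycorrhized arrays, BG646527 was well above background on 2 and LOC11431822 on 3, and 1 of the other 2 probes of LOC11407282 was not called. By the rule for naming, the 3 values of 1 group lay outside the range of the other for each transcript named here.

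Altogether 487 probes for 421 transcripts passed between mycorrhized and phosphate leaves (limma, adjusted p of 0.05), 290 higher and 197 lower in mycorrhized leaves, and 367 of them differed by at least 2-fold. The balance of directions was not kept under other settings, with 255 higher and 255 lower after quantile normalization, 259 and 248 in the authors' deposited table, 1253 and 1436 without control 3, and 1789 and 3072 with array row as a term. Higher calls stayed in the majority under others, with 150 and 70 after normexp correction, 328 and 124 on slide 1 alone, 366 and 198 without control 1 and 934 and 629 without mycorrhized 2. The same held without a filter, at 40 and 7, with the replicate block, at 1131 and 622, and with only the groups compared, at 623 and 472. The 487 probes include 88 genes with a symbol. Of the 88 called transcripts with several tested probes, 87 had all probes of 1 sign, but only 45 had all probes called. Groups did not overlap for 35.9% of tested probes, against 10% by chance on average over splits of the replicates. With a difference of at least 2 log2 units, 853 probes did not overlap as labelled and 373 in the highest other split. Of the probes higher in mycorrhized leaves, the control mean lay nearer the mycorrhized mean for 146 and nearer the phosphate mean for 144; of those lower, it lay nearer the mycorrhized mean for 68 and nearer the phosphate mean for 129. The named genes had adjusted p from 0.00867 for LOC11414535 to 0.0495 for LOC11429355. The count was 2689 without control 3 and 1563 without mycorrhized 2, 91 without control 2, 24 and 27 without mycorrhized 1 and 3, and 23, 19 and 20 without phosphate 1, 2 and 3. It was 47 without a filter, 1753 with the replicate block and 1095 with only the groups compared. With normexp correction the log2 fold changes were 4.19 for LOC11427346, 3.87 for LOC11417531, 5.33 for XM_003592090, 4.08 for EY475147, 1.63 for LOC11438646, 2.40 for LOC11442809, 5.15 for LOC11437154, 1.91 for LOC11429355 and 1.35 for LOC11415986, and -0.72 for LOC11414005, -1.29 for LOC11432675, -0.48 for LOC11431822 and for LOC11427949, -0.69 for LOC11414535, -2.83 for TA29873_3880 and -2.66 for BG646527; of these, LOC11427346, LOC11417531, LOC11442809, XM_003592090 and EY475147 still passed. Leaving out 1 replicate gave 4.63 for LOC11414355 (without mycorrhized 3), 5.05 for LOC11438646 (without phosphate 1), 4.70 for LOC11441531 and 4.63 for LOC11442809 (without phosphate 2) and 4.40 for LOC11443517 (without phosphate 3). XM_003592090 had 6.92, 5.46 and 6.76 without mycorrhized 2, phosphate 2 and phosphate 3, and BG646527 had -4.58 and -5.93 without mycorrhized 1 and 2. On slide 2 alone LOC11437154 had 9.73, XM_003592090 7.03 and LOC11427949 -2.02, and BG646527 had -4.30 on slide 1 and -7.35 on slide 2. The count was 452 on slide 1 alone, which lacks control 1, and 833 on slide 2 alone, which lacks mycorrhized 2. The fit to all 16 arrays, with its 1 correlation between arrays of a replicate, gave 4709 without slide and 4255 with slide as a term. Each transcript named for this comparison lost its call under 4 to 10 of 16 alternatives. Array row and group coincide in this comparison, so array row as a term takes the row difference from control 3 against controls 1 and 2. Any deviation of control 3 itself then counts as row. With that term 4861 probes passed, 285 of them among the 487, and 14 of the 24 named transcripts kept their calls. That term gave log2 fold changes of 9.44 for LOC11427346, 8.00 for LOC11414355, 6.80 for LOC11417531, 4.33 for LOC11417986, 12.31 for LOC11437154, 7.92 for LOC11429355 and 7.37 for EY475147, which were larger, and of 2.69 for LOC11442809 and 5.29 for XM_003592090. Among the falls it gave -3.27 for LOC11432675, -3.20 for LOC11407282, -2.48 for LOC11442101, -6.77 for BG646527, -2.02 for LOC11414005 and -2.61 for TA29873_3880. LOC11442809, XM_003592090, LOC11414005 and TA29873_3880 lost their calls with smaller changes, while LOC11443517 at 3.94 and LOC11412813 at -1.68 lost theirs with changes of like size. LOC11441531 at 3.87, LOC11415986 at 3.37, LOC11443098 at -1.27 and LOC11427949 at -1.10 also lost theirs.

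**Figure D3:**
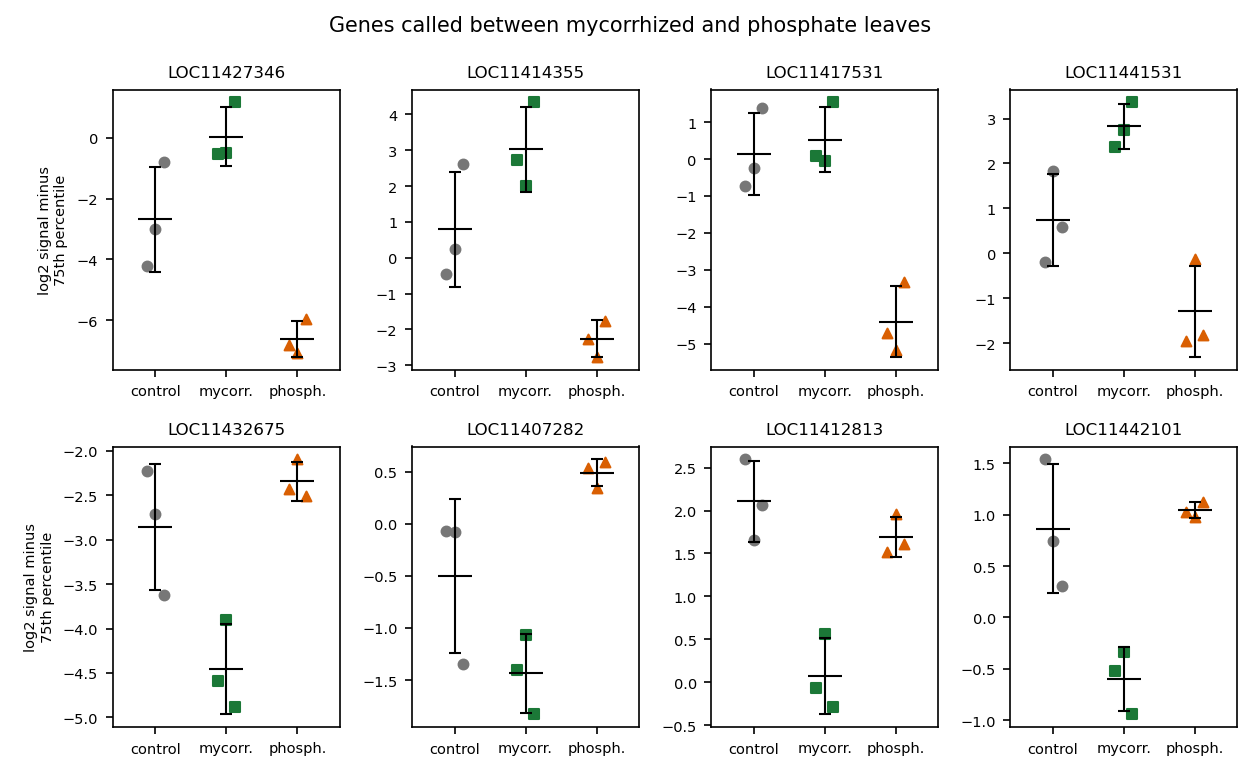
Normalized log2 signal (y axis, log2 signal minus the array's 75th percentile) of 8 genes called between mycorrhized and phosphate leaves, by group (x axis); points are the 3 biological replicates, horizontal bars the mean and error bars the SD. LOC11427346 stands at 0.04 in mycorrhized and -6.61 in phosphate leaves, with the 3 controls spread between -4.22 and -0.81.

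Between mycorrhized and control leaves no gene passed the test. The 10 genes with the smallest p are given as values. LOC11412329 had a log2 fold change of -5.18 (SE 0.44), from -0.76 ± 0.32 (SD, n = 3) in control to -5.94 ± 0.51 in mycorrhized leaves. LOC11412813 had -2.04 (SE 0.30), LOC11407356 -0.96, LOC11410978 -0.95 and LOC11413114 -0.81. LOC11446016 had 2.76 (SE 0.42), LOC11410928 2.05, LOC11434684 1.80, LOC11418006 1.58 and LOC11429131 1.16; LOC11418006 was well above background on 1 of 5 control arrays. Among transcripts with no symbol, TA20470_3880 had 1.67 (SE 0.18), NP7274037 1.03, TC186169 -2.32 (SE 0.23) and GE344759 -1.87. All these values had the 3 mycorrhized replicates on 1 side of the 3 controls, and adjusted p ran from 0.0885 to 0.176. LOC11413114 had another probe at -0.04. With normexp correction LOC11412329 had -3.21, LOC11446016 1.92 and LOC11418006 0.53; LOC11418006 also had 0.98 with quantile normalization, 0.90 with the authors' deposited table and 2.42 on slide 1 alone. LOC11412329 passed under 6 of 16 alternatives, among them the authors' deposited table and the fits without control 3 and without phosphate 3, with adjusted p from 0.00798 to 0.307 over the 16. All 14 transcripts named for this comparison passed without control 3. Array row as a term gave the same values, because in this comparison it removes control 3, so it is no separate setting. With slide as a term in the fit to 16 arrays 13 passed, all but LOC11418006.

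No probe passed an adjusted p of 0.05 in this comparison (limma), 7 had an adjusted p under 0.1, and 4091 had an unadjusted p under 0.05. Groups did not overlap for 16.4% of tested probes, against 10% by chance on average over splits of the replicates. Single splits vary widely, so this share alone does not show an effect of colonisation. Probes that did not overlap and differed by at least 2 log2 units numbered 246 as labelled. They numbered 1049 with control 3 and mycorrhized 2 exchanged, and 103 in the highest of the other splits. Without control 3, which leaves controls 1 and 2 and compares only arrays of row 1, 1419 probes passed, 631 higher and 788 lower in mycorrhized leaves; without control 2, 1 passed, and without phosphate 3, 3 passed. No probe passed on slide 1 or slide 2 alone. With slide as a term in a fit to all 16 arrays 488 passed, 284 higher and 204 lower in mycorrhized leaves. In that fit without slide 650 passed, 374 higher and 276 lower. Both take 1 correlation between arrays of a replicate for all probes.

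No probe was called in the same direction in both comparisons against control, where, with no probe called for mycorrhized leaves, the count and its value for independent lists (0) could only be 0. The log2 fold changes of the 2 comparisons correlated across probes at -0.06 (Pearson) and -0.06 (Spearman). Unchanged groups simulated with 3 shared controls gave a mean Pearson correlation of 0.50. The simulated controls were drawn probe by probe and are not the measured ones. They lack deviations that run through many probes, such as those of control 3. Their covariance was -0.0192, against 0.0775 in the simulations, a difference of -0.0966. Without control 3 the correlation was 0.35 and the covariance 0.174, where unchanged groups simulated against 2 shared controls gave means of 0.60 and 0.0814. In that fit 125 probes were called in the same direction in both, where the simulated unchanged groups shared 0 and independent lists would share 5.71; neither value covers changed probes compared with the same controls. As 3 controls cannot be divided into separate sets of at least 2, the part that the shared controls add was addressed by simulation only. With probes drawn independently, the simulation does not measure that part for these controls.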

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

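The alternatives that leave out 2 arrays, control 3 with mycorrhized 2, or add array row were chosen after seeing the data. Counts of probes are given in the order mycorrhized against control (0 in the report), phosphate against control (44) and mycorrhized against phosphate (487), followed by the number called in the same direction in both comparisons against control (0). Unless a reason is given, the cause was not tested.

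With quantile normalization 1, 42 and 510 probes passed, and with the authors' values 1, 42 and 507, with 1 shared in each. Between mycorrhized and phosphate leaves, higher and lower calls numbered 255 and 255, and 259 and 248, against 290 and 197; they were 313 and 319 with the filter on all 16 arrays, 2239 and 2470 with the random block and 2032 and 2223 with slide. Of the 44 probes, 40 were kept under either, and of the 487, 412 and 414. Normexp correction gave 4, 24 (1 higher, 23 lower) and 220, with 2 shared. Without a filter, which tests more probes, the counts were 0, 22 and 47. The filter on all 16 arrays tests fewer and gave 0, 24 and 632. The fit to 16 arrays with replicate as a random block gave 650, 266 and 4709 with 33 shared, and with slide as a term 488, 195 and 4255 with 23 shared; both take 1 correlation between arrays of a replicate (0.862 and 0.884) for all probes. Slide 1 alone gave 0, 19 and 452 and slide 2 alone 0, 36 and 833, with fewer arrays. Only the groups compared gave 1, 33 and 1095. Array weights gave 27108, 9274 and 17383 with 5501 shared; their estimation stopped before it converged, with weights from 0.0872 for control 3 to 110.3 for control 2, so these counts rest on few replicates. The variance trend gave 0, 44 and 658. An adjusted p under 0.01 left 0, 19 and 24, and a fold of at least 2 left 0, 43 and 367.

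Leaving out 1 replicate gave 0 to 1419, 19 to 230 and 19 to 2689 probes, with 0 to 125 shared, the highest each time without control 3; where this leaves 2 replicates, they are assumed to vary like the other groups. Leaving out the 2 arrays with the most probes well above background gave 1, 47 and 784 with 1 shared. Array row as a term gave 1419, 37 and 4861 with 2 shared, and kept 15 of the 44 and 285 of the 487; the 37 were 16 higher and 21 lower, against 8 and 36. Only the controls lie in both rows, so for mycorrhized against control this term removes control 3 by construction. Without control 3 and mycorrhized 2 together, 8175, 352 and 9327 passed with 230 shared, but these replicates were left out because of where their values lay, which raises the counts.

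Replicates numbered 2 and 3 went together with those of the same number in the other groups, while those numbered 1 did not. Deviations from the group means correlated at -0.20, 0.44 and 0.59 between control and mycorrhized replicates 1, 2 and 3, at 0.05, 0.34 and 0.35 between control and phosphate, and at -0.09, 0.46 and 0.40 between mycorrhized and phosphate, and control 1 correlated better with mycorrhized 2 (0.52) than with mycorrhized 1. Between groups, replicates 2 and 3 correlated negatively, for example at -0.59 for control 3 with mycorrhized 2 and -0.47 for mycorrhized 3 with phosphate 2. Whether replicates of 1 number share a cause was not tested. With the replicate block the counts were 0, 29 and 1753 with 0 shared, and 22 of the 44 and 484 of the 487 probes were kept.

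Fold changes of the named transcripts had the same sign under all 16 alternatives run for each. Of 784 such values, 507 kept their side of the threshold, 245 lost the call and 32 gained it, 14 of these without control 3 and 13 with slide as a term. Gene list alternatives were not run, as no list had members. Dim probes limit the fold sizes, as given above for LOC11418309 with normexp correction.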

Other observations

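The tests of an exchange of samples, of slide and of array row were chosen after the values they rest on had been seen at least in part, as were the alternatives that leave out 2 arrays or control 3 with mycorrhized 2; the other tests were chosen before.

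The only tested gene with a descriptive name was RDN2 (LOC11443987), given here for its name alone. Its 2 probes had log2 fold changes of 0.43 and 0.58 between mycorrhized and phosphate leaves, with adjusted p of 0.363 and 0.260 (limma), and of 0.14 and 0.18 between mycorrhized and control leaves, with adjusted p of 0.830 and 0.780.

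Control 3 lay with mycorrhized 1 and 3, and mycorrhized 2 lay nearer controls 1 and 2 than they did. The slides argue against a slide or scan effect, since control 3 correlated better with mycorrhized 1 and 3 than with control 2 on both, by 0.0150 and 0.0233. Dim probes and background are argued against too, since over the brightest 25% of probes the difference of correlations from controls 1 and 2 was 0.0789, against at most 0.0032 lost between arrays of 1 replicate. An exchange of control 3 and mycorrhized 2 stays open: 246 probes separated the groups by at least 2 log2 units as labelled, more than the 103 of the highest of the 8 splits that are neither labelled nor exchanged, but 1049 did so in the exchanged split, and the labelled split is only 1 of 9 splits that differ from it by 1 pair, so leading them does not exclude an exchange, although the bound written for this test had said it would. A difference among the plants unrelated to the treatments, such as growth state, stays open as well and was not tested.

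No probe passed between mycorrhized and control leaves while 487 passed between mycorrhized and phosphate leaves. The 2 arrays with the most probes well above background, of which 1 had a raised median background (170.0), are argued against as the source, since without them 1 probe passed against 784; the bound written beforehand, of at least 1 probe, was met but was too low to account for the gap. The spread among the controls may account for it, since 1419 probes passed without control 3 and at most 1 without control 1 or 2, but control 3 was singled out by its place near mycorrhized 1 and 3, which raises that count. Array row cannot be told apart from group here. Over the 487 probes the median size of the difference between mycorrhized and phosphate leaves was 1.47 log2 units. In the direction of these differences, controls of row 1 differed from the control of row 2 by a median of -0.12. This value cannot decide on row, as a single control lies in row 2. That control also lies with mycorrhized 1 and 3, which would lower the value. The replicates of the rows part on PC2. A smaller effect of colonisation than of phosphate was not tested as such and stays open, although 4091 probes, against 2612 for phosphate, had an unadjusted p under 0.05 with all controls.

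Changed genes were tested for lying beside each other in the genome. Among 4134 measured genes, the 88 called between mycorrhized and phosphate leaves formed 2 pairs within 5 gene positions, counting a gene as called if any of its probes passed, against a mean of 1.84 in 10000 random draws (permutation p = 0.548, one-sided), so no clustering was detected.

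Other splits of the 6 replicates into 3 and 3 number 10 per comparison with the real one, too few for a share under 0.05. Between mycorrhized and control leaves the real split gave 0 probes, so that all 10 gave as many, and the highest other gave 7482; that was the split that exchanges control 3 and mycorrhized 2, which points to a structure of the samples that crosses the groups. Between phosphate and control leaves the real split gave 44 probes, and the highest other 0, so that 1 split gave as many. For mycorrhized against phosphate leaves these values were 487, 0 and 1.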
